A study of Homo sapiens with 2 samples.

How the data were processed

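RNA from HCT-116 cells, an established human colorectal carcinoma line, was sequenced as 1 library of untreated cells and 1 library of cells treated with lysophosphatidic acid (LPA) at 10 µM for 24 h after serum starvation. Whether the control cells were also serum starved is not given here. LPA is a signalling phospholipid that acts through G protein-coupled receptors. Per the labels' protocols, RNA was extracted with Trizol, enriched for poly-A RNA and made into libraries with the TruSeq V2 kit, which does not mark strand. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart. Both groups were assigned from the sample titles.

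The submitters' processing notes name bcl2fastq 2.16.0.10, TopHat2 2.0.12, Cufflinks (version not given in the sources used here) and Cuffdiff 2.2.0, with the hg38 genome build. Their settings, and how the libraries were scaled against each other, are not given in the sources used here. The deposited values are FPKM, estimated fragment numbers scaled by transcript length and library size, for each of 63236 isoforms, in the layout of a Cuffdiff isoform table, per the file headers. The table gives each isoform's nearest RefSeq transcript, length, FPKM, a lower and an upper FPKM bound and a status in each library. The level of these bounds is not stated in the file. They come from the authors' software and hold no replicate error measured within a group. Of the isoforms, 6304 carry the class code j, meaning a splice pattern that differs from the RefSeq transcript. No column of sample values was left unused.

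In the LPA library 16 isoforms have the status HIDATA, given by the software to loci with too many fragments to process, and 11 have the status FAIL. All isoforms in the control library have the status OK. The HIDATA isoforms hold no estimate in the LPA library and are listed at 0 there, so they were treated as missing. This departs from the plan made before the data were examined, which was to use all isoforms. Keeping them at 0 was added as an alternative after seeing the data.

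Isoform FPKM were summed per gene symbol, giving 26257 symbols, of which 1296 had isoforms at more than 1 locus. The comparison used the 11688 genes with a mean FPKM over both libraries of at least 1. A gene's log2 ratio is log2((LPA FPKM + 1)/(control FPKM + 1)), which understates differences in genes with low FPKM. Genes were counted as at least 2-fold apart at a log2 ratio of 1 or more in size. Coordinates are the loci of the deposited table in hg38, written with 1-based starts. Such a locus can extend beyond the gene it is named for.

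No read counts were used, so depth was estimated from the FPKM themselves. Among genes with 1 isoform longer than 2000 nt, the lowest values of FPKM multiplied by length clustered at 0.0597 in the control and 0.0637 in the LPA library, taken as the worth of 1 fragment. This gave about 16800000 fragments for the control and 15700000 for the LPA library. At that depth 1 FPKM on an isoform of 2 kb corresponds to about 33.5 and 31.4 fragments. Poisson draws around the mean of both libraries (100 draws) put a median of 0 and at most 3 genes past 2-fold on either side, and gave a robust SD of the log2 ratio of 0.06 among genes at mean FPKM of 5 or more. These estimates cover counting error only, and the observed robust SD among the same genes was 0.24.

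Before the data were examined 33 gene lists were fixed. They cover LPA receptors, LPA synthesis and breakdown, the immediate early response, ERK output, targets of SRF and MRTF, of YAP and TAZ, of NF-kB, of beta-catenin, of p53, of interferon, of TGF-beta and of FOXO factors in quiescence, G1/S and DNA replication, G2/M and mitosis, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, the ATF4 and amino acid response, endoplasmic reticulum chaperones, heat shock, epithelial junctions, mesenchymal markers, invasion proteases, intestinal differentiation, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, the mitochondrial genome, histones, reference genes, and fibroblast, immune and endothelial markers. For the 28 lists with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. A list was called apart when its median lay outside the central 95% range of those medians, and about 1.40 of 28 unrelated lists would do so by chance. A percentile describes these libraries and is not a p-value, since members of a list are not independent. Another 6 lists (RNAs without a poly-A tail, a wider set of histones, cytosolic and mitochondrial aminoacyl-tRNA synthetases, keratins and one-carbon enzymes) were drawn up after values had been seen.

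Isoforms were compared among the 16999 with mean FPKM of at least 1 and status OK, and were counted when they were at least 2-fold apart with deposited bounds that did not overlap. A gene was counted as having another leading isoform when it had a mean FPKM of at least 5, at least 2 isoforms, a different isoform with the highest share in each library, and a shift in share of at least 30 percentage points.

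The genes named by rule are the 12 highest and 12 lowest log2 ratios at mean FPKM of 5 or more (status OK and a longest isoform of at least 300 nt), up to 4 members per list with the log2 ratios farthest from 0, every LPA receptor, ACTB and GAPDH, and the 5 genes with the biggest shift in isoform share. Other list members are named as examples after their values were seen. A few of these genes are not reported here, but they stayed in the counts and list medians.

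GC content was taken from GENCODE 29 transcripts through the RefSeq identifier of each gene's leading isoform (24537 genes) or its symbol (1016 genes), and 704 genes were not matched. Of the compared genes 99.2% had a value. Log2 ratios were adjusted by lowess curves (fraction 0.3) on GC content and then on log2 length, an alternative chosen after seeing the data. The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter or a filter at mean FPKM 5, centring on the median of all genes or of the reference genes, rescaling both libraries to a common sum as in TPM, the leading isoform alone, status OK isoforms alone, leaving out isoforms under 300 nt, sums per gene identifier, and other limits for the isoform counts.

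The procedure was tested on simulated data for this comparison, with 11688 genes. Of 50 genes simulated at each size, 2% passed the 2-fold limit at a true 1.5-fold difference, 32% at 2-fold, 90% at 3-fold and 100% at 4-fold. Of 200 unchanged lists of 15 genes 8 were called apart, as were 50 of 50 lists shifted by 0.3 on the log2 scale. The simulated noise was independent between genes and list members were drawn at random. These rates therefore need not hold for real lists, whose members can vary together. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.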

Results

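Poly-A RNA was profiled in HCT-116 colorectal carcinoma cells to ask how transcript levels differ between untreated cells and cells given LPA at 10 µM for 24 h after serum starvation. The data used here are 1 library per condition, without replicates, and both sample titles carry the number 3. Whether other replicates exist is not known here. Every difference below is therefore between these 2 libraries and has no replicate check and no p-value. The FPKM of all isoforms summed to 718801 in the control and 709125 in the LPA library, and 11692 and 11642 genes reached 1 FPKM. The 10 most abundant genes held 11.8% of the FPKM in the control library and 11.5% in the LPA library.

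In the LPA library, genes of the amino acid and ATF4 response stood out most, with CHAC1, SLC7A5, PSAT1, ASNS and ATF4 itself all higher. The contractile genes MYL9 and TAGLN, the carboxypeptidase gene CPA4, genes of DNA replication and genes of ribosome biogenesis were also higher. Lower in the LPA library were SEPP1, which encodes the selenium carrier selenoprotein P, the glucose transporter gene SLC2A1, the Wnt ligand gene WNT16 and genes linked to quiescence such as CCNG2 and BNIP3. The lists of immediate early genes, of ERK output genes and of NF-kB targets with chemokines had medians inside the range of random lists at this time point. Most of the transcriptome differed little, with a Pearson correlation of 0.983 between the libraries across 11688 genes, which are not independent replicates.

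Of these genes 41 were at least 2-fold higher and 24 at least 2-fold lower in the LPA library. Small RNAs made up much of both sets: the leading isoform was under 300 nt for 17 of the higher and 17 of the lower genes, and 13 and 14 genes respectively were listed at 0 in one of the libraries. SNORD22 and SNORA40, for example, were listed at 0 in the control and at 144 and 130 FPKM in the LPA library, whereas SNORA38 and SNORA63 were at 57.3 and 56.6 FPKM in the control and listed at 0 in the LPA library. Such isoforms are short (126 nt for SNORD22 and 127 nt for SNORA40), so their values are uncertain and a listed 0 need not mean absence. Without isoforms under 300 nt the counts were 24 higher and 7 lower. Protein-coding genes with a leading isoform of 300 nt or more accounted for 19 of the higher genes by the annotation used. Among the lower genes they included KLRC3, a natural killer receptor gene named here after its values were seen (6.38 and 2.54 FPKM), and SEPP1, whose symbol was not matched in that annotation. The median log2 ratio over all genes was 0.0009, and 95% of genes lay between -0.51 and 0.49. At a 1.5-fold limit 169 genes were higher and 180 lower.

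**Figure D1:**
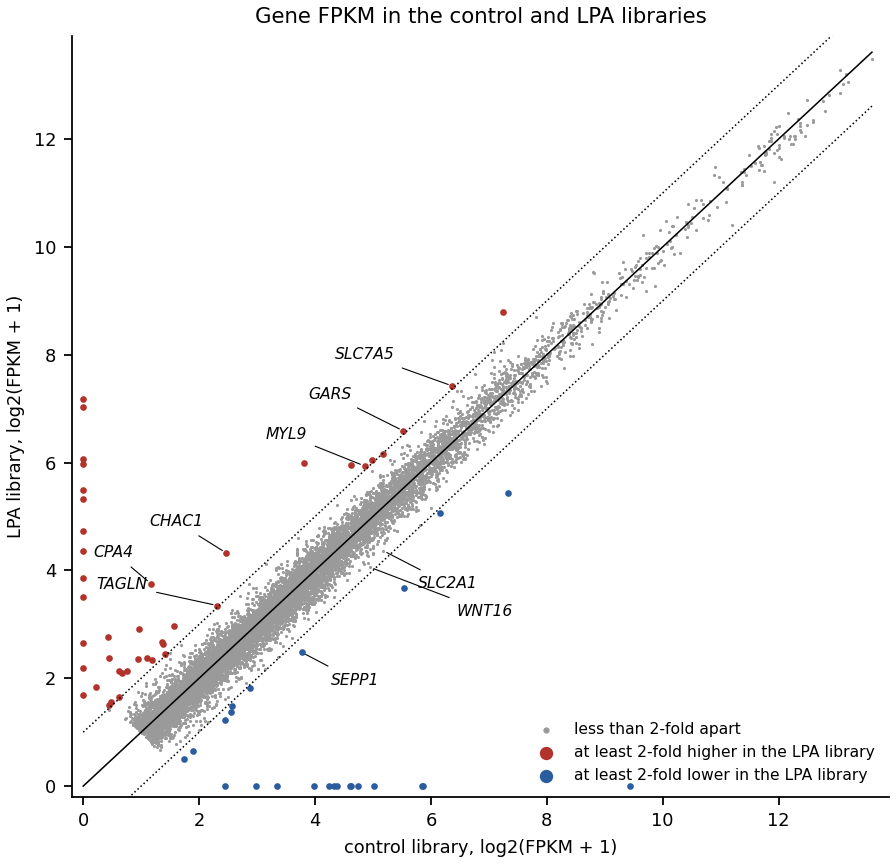
Log2(FPKM + 1) of each of 11688 genes in the control library (x axis) and the LPA library (y axis), with the solid line at equality and dotted lines at 2-fold. The 41 red genes are at least 2-fold higher and the 24 blue genes at least 2-fold lower in the LPA library, and those on the axes are listed at 0 in one library.

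Among genes with a mean FPKM of at least 5 and a longest isoform of at least 300 nt, CPA4, a zinc carboxypeptidase gene on chromosome 7 (130293134 to 130324180), had the highest log2 ratio, at 2.59, with 1.25 FPKM in the control and 12.5 FPKM in the LPA library. CHAC1, whose product degrades glutathione, followed on chromosome 15 (40953438 to 40956519) with 4.53 and 19.0 FPKM (log2 ratio 1.86). GARS, the glycyl-tRNA synthetase gene on chromosome 7 (30594565 to 30634032), had 45.0 and 95.2 FPKM. SLC7A5, the light chain of a transporter of large neutral amino acids on chromosome 16 (87830023 to 87869494), had 81.8 and 170 FPKM. PSAT1, an enzyme of serine synthesis on chromosome 9 (78297075 to 78330093), had 34.9 and 70.8 FPKM, and CST6, which encodes the protease inhibitor cystatin E/M, had 57.7 and 109 FPKM. MYL9, a myosin regulatory light chain gene (27.9 and 60.3 FPKM), and TAGLN, an actin-binding protein gene (3.97 and 9.18 FPKM), had log2 ratios of 1.08 and 1.03. The remaining 4 of the 12 highest were RPPH1 and RN7SK, 2 RNAs without a poly-A tail, and EIF4EBP3 and P2RY11. EIF4EBP3 lies in a locus with ANKHD1 and P2RY11 in a locus with PPAN, and each also shares it with a read-through transcript, so the split of fragments among these genes is uncertain. The deposited bounds of the leading isoform were separate between the libraries for 8 of the 12 highest genes, and overlapped for MYL9, TAGLN, EIF4EBP3 and P2RY11.

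At the other end of the same set of genes, SEPP1 on chromosome 5 (42756818 to 42811922) had the lowest log2 ratio, -1.29, with 12.6 FPKM in the control and 4.59 FPKM in the LPA library. TANK, which encodes a TRAF-binding regulator of NF-kB signalling, had 55.4 and 27.8 FPKM. WNT16 on chromosome 7 (121325367 to 121341104) had 29.7 and 15.7 FPKM, and SLC2A1, the main glucose transporter gene of many cancer cells, on chromosome 1 (42925375 to 42983358), had 35.0 and 19.7 FPKM. Also among the 12 lowest were SDHAF4, an assembly factor of succinate dehydrogenase (9.30 and 4.26 FPKM), NIPSNAP3A (7.75 and 3.50 FPKM) and BDH2, a hydroxybutyrate dehydrogenase gene (9.85 and 5.06 FPKM). FAM175A, part of a BRCA1 complex, had 11.1 and 5.69 FPKM, TOM1L1, an endosomal adaptor gene, 19.2 and 10.4 FPKM, and the uncharacterised LOC100506844 7.64 and 3.77 FPKM. AHRR, the aryl hydrocarbon receptor repressor gene, had a log2 ratio of -0.84 but shares its locus with PDCD6, and the read-through RPL17-C18orf32 shares its locus with RPL17 and C18orf32, so both values are uncertain. Bounds were separate for 5 of the 12 lowest genes: SEPP1, NIPSNAP3A, WNT16, BDH2 and SLC2A1. The median GC content was 59.7% for the 12 highest and 42.9% for the 12 lowest genes, and all of them with a GC value (12 and 11 genes, without SEPP1) kept the sign of their log2 ratio after adjustment for GC content and length.

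**Figure D2:**
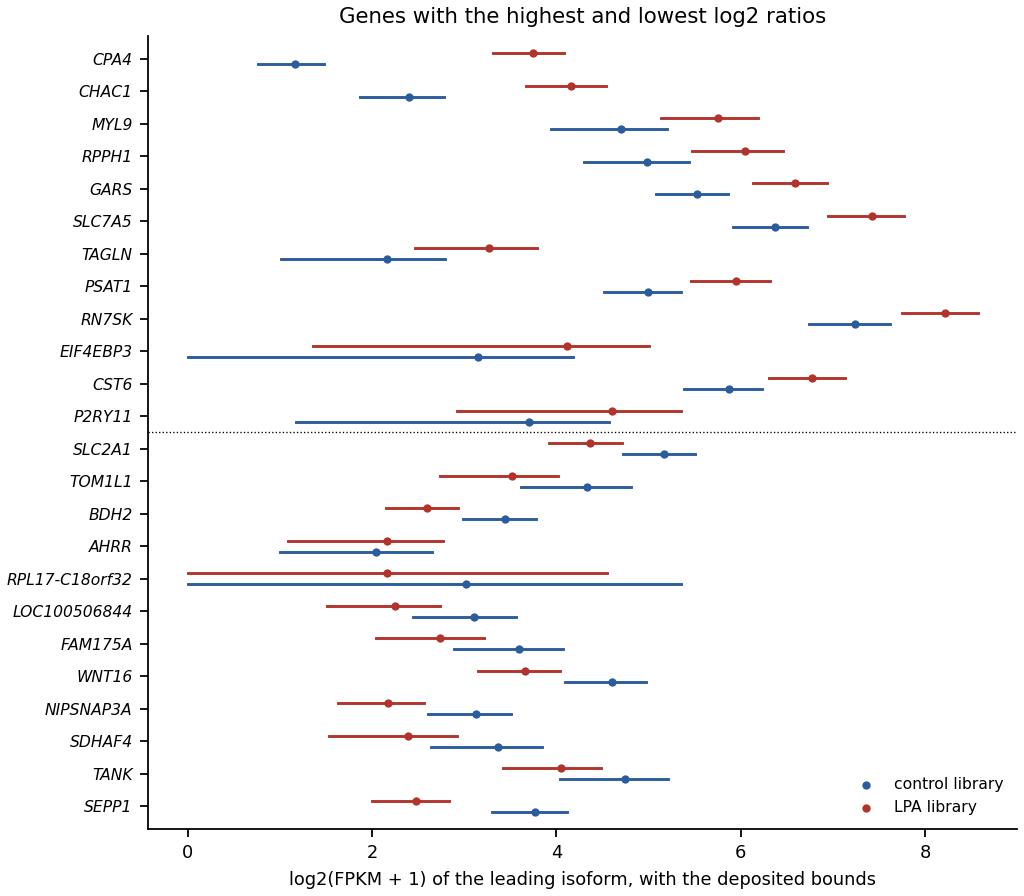
Log2(FPKM + 1) of the leading isoform (x axis) of the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with mean FPKM of at least 5 and a longest isoform of at least 300 nt. Points are the control (blue) and LPA (red) libraries, lines are the deposited bounds, which do not overlap for 8 of the upper and 5 of the lower genes.

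Among the 28 gene lists with enough measured members, 4 had medians above the central 95% range of matched random lists and 1 had a median below it. In the ATF4 and amino acid response list, 15 of 17 measured genes had a log2 ratio above 0, with a median of 0.65 (percentile 100). In this list 3 genes were at least 2-fold higher (1 when centred on the reference genes, 2 when centred on the median of all genes or with a pseudocount of 5). ATF4, the transcription factor of this response, had 449 and 730 FPKM. ASNS, asparagine synthetase, had 86.3 and 160 FPKM, SLC3A2, the heavy chain partner of SLC7A5, 148 and 271 FPKM, and the cystine transporter gene SLC7A11 2.29 and 4.38 FPKM. Other members differed less: DDIT3, which encodes the factor CHOP, had 16.9 and 19.4 FPKM, and CEBPB 74.1 and 71.3 FPKM. Chaperones of the endoplasmic reticulum had a list median of 0.10 (percentile 77.5), although HSPA5 (99.1 and 145 FPKM), HERPUD1 (16.8 and 26.0 FPKM) and SDF2L1 (73.0 and 111 FPKM) had log2 ratios of 0.55 to 0.60. DNAJB9, another of these chaperones, was lower (8.25 and 6.57 FPKM).

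In the list of SRF and MRTF targets, which holds genes of the actin cytoskeleton, 14 of 18 measured genes had a log2 ratio above 0 and the median was 0.25 (percentile 100). Beside MYL9 and TAGLN, the myosin heavy chain gene MYH9 had 40.1 and 64.2 FPKM and ACTG1 1916 and 2868 FPKM. ACTB, also on the list of reference genes, had 805 and 1188 FPKM, while the reference gene GAPDH had 4133 and 4852 FPKM. Actin genes and GAPDH have many pseudogenes that can share reads. SRF itself had 19.4 and 18.3 FPKM. With the leading isoform standing for each gene, this list's median was 0.14 and no longer outside its random range. YAP and TAZ targets, another group linked to the cytoskeleton, had a median of 0.02 (percentile 72.6), with AXL at 5.30 and 7.50 FPKM, DOCK5 at 1.11 and 1.88 FPKM, NT5E at 11.1 and 13.7 FPKM and AJUBA at 9.95 and 6.84 FPKM.

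Genes of G1/S and DNA replication were higher in the LPA library in 17 of 20 cases, with a median of 0.29 (percentile 99.98). The replication factor gene MCM10 had 2.80 and 4.76 FPKM, the transcription factor gene E2F1 9.31 and 14.2 FPKM, GINS2 29.6 and 42.0 FPKM and the uracil glycosylase gene UNG 34.0 and 47.3 FPKM. Genes of G2/M and mitosis were split, 12 higher and 8 lower with a median of 0.03 (percentile 47.5). Among them, MKI67 (13.2 and 20.1 FPKM) and AURKB (41.1 and 55.9 FPKM) were higher, and TOP2A (21.4 and 14.4 FPKM) and CDK1 (67.5 and 50.2 FPKM) lower. RNA polymerase I and ribosome biogenesis genes were higher in 15 of 17 cases (median 0.28, percentile 99.98), among them PES1 (65.9 and 102 FPKM), DKC1 (47.1 and 69.7 FPKM), NOP56 (102 and 147 FPKM) and RRS1 (29.1 and 41.7 FPKM). Cytosolic ribosomal protein genes had a median of -0.01 (percentile 31.4), from RPL32 at -0.23 to RPL18 at 0.30, with RPL8 at 0.24 and RPS16 at 0.23. Their pseudogenes can share reads.

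The quiescence and FOXO list was the 1 list below its random range, with 11 of 14 genes lower and a median of -0.17 (percentile 1.78). CCNG2, an atypical cyclin gene, had 8.98 and 5.38 FPKM, the mitophagy receptor gene BNIP3 47.0 and 31.3 FPKM, and the pocket protein gene RBL2 3.99 and 3.26 FPKM, whereas the insulin receptor gene INSR had 3.24 and 3.97 FPKM. TXNIP, another member, was listed at 0 in both libraries, which need not mean absence. BNIP3 is also a hypoxia gene. The hypoxia and glycolysis list had a median of -0.07 (percentile 11.2), with SLC2A1, ANKRD37 (7.26 and 4.03 FPKM) and BNIP3 lower and the phosphofructokinase gene PFKP higher (78.6 and 109 FPKM).

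Both lipid synthesis lists had medians inside the central 95% range of their random lists, and no member was 2-fold lower. In the cholesterol list 15 of 20 genes had a log2 ratio below 0 (median -0.08, percentile 4.76), among them IDI1 (181 and 125 FPKM), LSS (47.6 and 34.2 FPKM) and SC5D (13.8 and 10.3 FPKM). In the fatty acid list 9 of 12 were below 0 (median -0.12, percentile 5.23), with ELOVL6 (52.5 and 35.0 FPKM), ELOVL5 (52.4 and 37.6 FPKM) and the regulator SREBF1 (68.8 and 51.0 FPKM) lower and ACACA higher (15.3 and 18.6 FPKM). Interferon response genes had a median of -0.14 (percentile 5.58) and went both ways: ISG15, a ubiquitin-like modifier gene, had 223 and 412 FPKM and IFI27 4.96 and 8.57 FPKM, while IFIT1 had 2.19 and 0.785 FPKM and IFIT3 1.43 and 0.761 FPKM. After adjustment for GC content and length the fatty acid and interferon lists lay below the central 95% range of their random lists, with medians of -0.17 and -0.21.

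**Figure D3:**
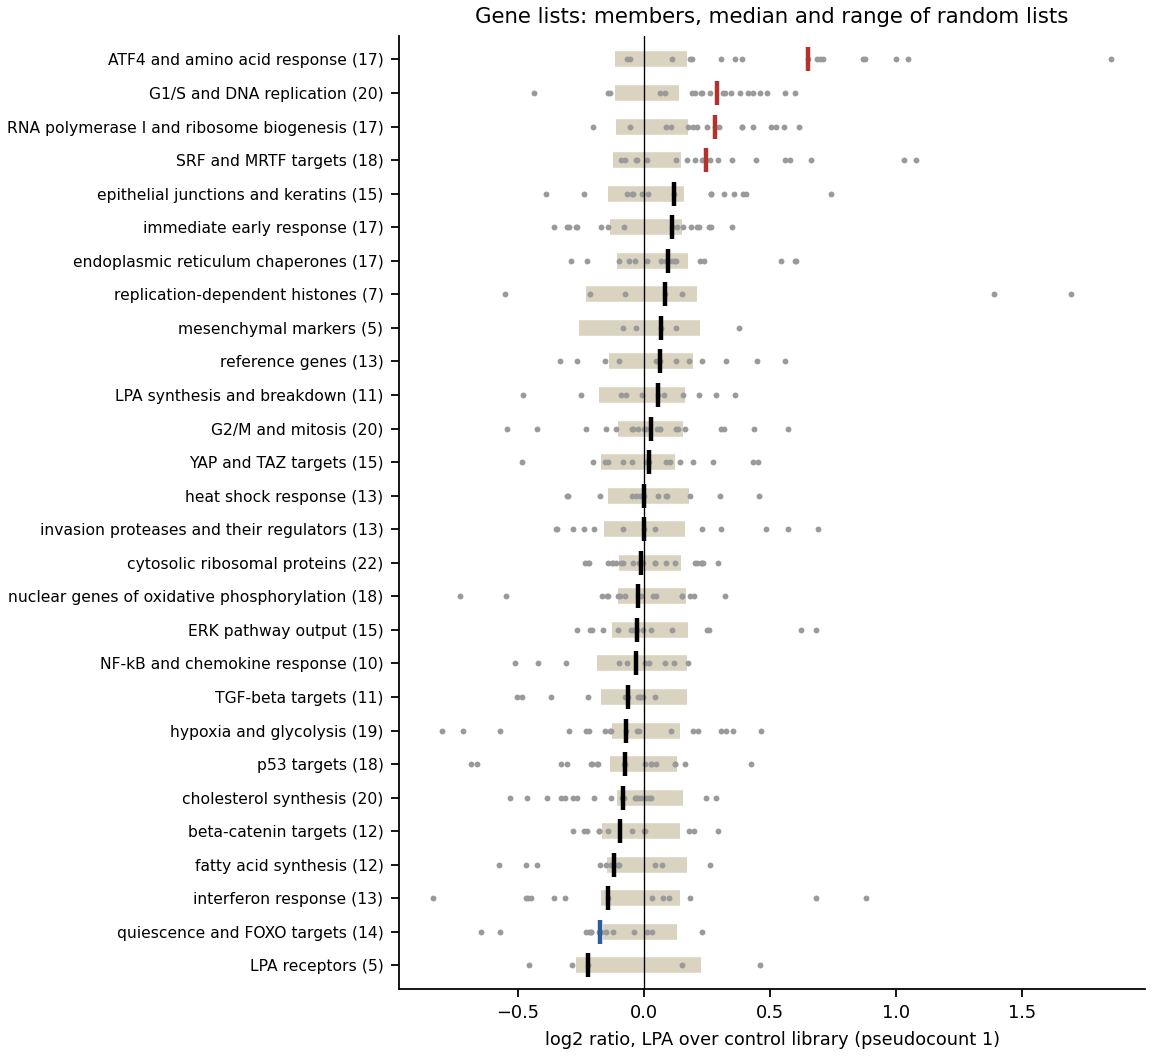
Log2 ratio (x axis, LPA over control library) of the measured members (grey points) of 28 gene lists, with each median as a vertical bar and the central 95% of medians of 10000 matched random lists as a pale band. Red bars mark the 4 lists above and the blue bar the 1 list below the random range, and numbers in brackets are measured members.

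Of the LPA receptor genes LPAR2 had the highest FPKM, with 15.6 FPKM in the control and 21.9 FPKM in the LPA library. LPAR3 had 5.38 and 6.09 FPKM, LPAR1 3.32 and 2.54 FPKM and LPAR5 3.61 and 2.95 FPKM, and LPAR4, LPAR6 and P2RY10 were listed at 0 in both libraries, which need not mean absence. The 5 measured receptors, 3 of them below 0, had a median log2 ratio of -0.22 (percentile 5.44), inside the random range, and with the leading isoform standing for each gene the median was 0.15. Genes of LPA synthesis and breakdown had a median of 0.06 (percentile 73.1), with the acyltransferase genes LPCAT1 (28.9 and 37.5 FPKM) and AGPAT2 (58.5 and 71.6 FPKM) higher and the kinase gene AGK (11.3 and 7.83 FPKM) and the phosphatase gene PPAP2B (1.26 and 0.900 FPKM) lower.

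The lists of immediate early genes, ERK output and targets of NF-kB, beta-catenin and TGF-beta had medians inside their random ranges. Immediate early genes had a median of 0.11 (percentile 91.2), with ATF3 at 10.1 and 13.1 FPKM but FOS at 5.20 and 4.05 FPKM, JUNB at 154 and 125 FPKM and BTG2 at 14.9 and 11.4 FPKM. ERK output genes had a median of -0.03 (percentile 22.4). Within that list the AP-1 subunit gene FOSL1 (48.1 and 77.9 FPKM), EMP1 (9.75 and 15.6 FPKM) and IER3 (608 and 728 FPKM) were higher, and the phosphatase gene DUSP6 (70.4 and 58.4 FPKM) lower. NF-kB targets and chemokines, with 10 of 19 genes measured, had a median of -0.03 (percentile 37.2). BIRC3 (7.59 and 5.03 FPKM), CXCL8 (2.86 and 1.89 FPKM) and CXCL1 (2.44 and 1.78 FPKM) were lower and NFKB2 (51.5 and 58.2 FPKM) higher. Beta-catenin targets had a median of -0.09 (percentile 13.5), with AXIN2 at 3.07 and 2.48 FPKM, SP5 at a log2 ratio of -0.24, EPHB3 at 2.48 and 1.87 FPKM and EPHB2 at 1.98 and 2.66 FPKM. TGF-beta targets had a median of -0.06 (percentile 21.2) with 10 of 11 genes below 0, among them the inhibitor genes ID3 (95.1 and 66.9 FPKM) and ID2 (72.5 and 51.6 FPKM), TGIF1 (85.5 and 65.9 FPKM) and CDKN2B (2.31 and 1.84 FPKM). With genes at mean FPKM of 5 or more alone, the TGF-beta list had a median of -0.22, below its random range.

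Invasion proteases and their regulators had a median of 0.00 (percentile 46.5). The urokinase receptor gene PLAUR (23.6 and 38.8 FPKM), the protease inhibitor gene TIMP1 (159 and 237 FPKM) and HBEGF (3.05 and 4.68 FPKM) were higher, while urokinase itself, PLAU, was lower (23.8 and 18.4 FPKM). Epithelial junction and keratin genes had a median of 0.12 (percentile 91.6), with KRT18 (442 and 741 FPKM), DSP (11.9 and 16.0 FPKM) and CLDN7 (121 and 159 FPKM) higher and CLDN4 (210 and 160 FPKM) lower. At mean FPKM of 5 or more this list had a median of 0.20, above its random range. Mesenchymal markers had 5 measured members, 3 above and 2 below 0, and a median of 0.07 (percentile 74.1). Of the intestinal differentiation list only 4 genes were measured, too few for a percentile: CDX2 (9.41 and 10.5 FPKM), CA2 (10.5 and 8.45 FPKM), DPP4 (3.99 and 3.03 FPKM) and KRT20 (1.22 and 1.16 FPKM).

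Targets of p53 had a median of -0.08 (percentile 11.6), with GDF15 (273 and 366 FPKM) higher, TP53INP1 (6.54 and 3.69 FPKM), RRM2B (16.2 and 9.88 FPKM) and DDB2 (21.9 and 17.2 FPKM) lower, and CDKN1A at 141 and 144 FPKM. Heat shock genes had a median of 0.00 (percentile 41.2), with HSP90AA1 (803 and 651 FPKM) and DNAJA1 (207 and 168 FPKM) lower and the near-identical pair HSPA1A (1.37 and 2.25 FPKM) and HSPA1B (38.8 and 48.2 FPKM), which share reads, higher. Nuclear genes of oxidative phosphorylation had a median of -0.02 (percentile 21.9), with NDUFS1 (22.5 and 13.2 FPKM) and NDUFA4 (110 and 74.9 FPKM) lower and UQCRC1 (149 and 187 FPKM) and NDUFB8 (249 and 287 FPKM) higher. Reference genes had a median of 0.07 (percentile 62.7), from VPS29 (71.9 and 56.9 FPKM) to CHMP2A (70.7 and 96.9 FPKM) and ACTB. Genes of the mitochondrial genome were not analysed here.

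Of 10 fibroblast markers only the collagen gene COL1A1 (5.75 and 4.28 FPKM) and of 12 immune markers only the macrophage gene CD68 (2.64 and 2.85 FPKM) had a mean of at least 1 FPKM. No endothelial marker was above 0.285 FPKM. RNAs mostly without a poly-A tail, histones left out, were put in a list after values had been seen. Of its 17 measured members, 12 had a log2 ratio above 0 and 5 below. The median was 0.20 (percentile 99.7), above the random range of -0.14 to 0.15, with RN7SK and RPPH1 among the members. Some members are short isoforms listed at 0 in one library, so their values are uncertain. RN7SK, a regulator of transcription elongation, had 150 and 297 FPKM and RPPH1, the RNA of ribonuclease P, 30.6 and 65.1 FPKM, whereas the signal recognition particle RNAs RN7SL1 (2343 and 1353 FPKM) and RN7SL2 (3890 and 2363 FPKM) were lower in the LPA library. Replication-dependent histone genes, whose RNA mostly lacks a poly-A tail, had a median of 0.08 (percentile 78.2). HIST1H1E had 0.683 and 3.41 FPKM, and HIST1H4C was listed at 0 in the control and at 2.24 FPKM in the LPA library. HIST1H2AC (17.6 and 11.7 FPKM) and HIST1H2BD (14.4 and 12.3 FPKM) were lower, and whether their RNA here carried a poly-A tail is not known. Ribosomal RNA loci, among them RNA28S5 at 655 FPKM in the control, had no estimate in the LPA library because of the HIDATA status.

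Log2 ratios were related to transcript GC content across genes (Spearman 0.30 over 11596 genes, which are not independent replicates). Genes were put into 10 bins of equal size by GC content. The bin with the lowest GC content, 31.8 to 39.2%, had a median log2 ratio of -0.19, and the bin from 50.3 to 53.5% had a median of 0.09. After adjustment the correlation was 0.02. The 5 lists named above stayed outside their random ranges after adjustment, with medians of 0.61 for the ATF4 and amino acid response, 0.31 for ribosome biogenesis, 0.27 for G1/S, 0.19 for SRF and MRTF targets and -0.19 for quiescence.

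**Figure D4:**
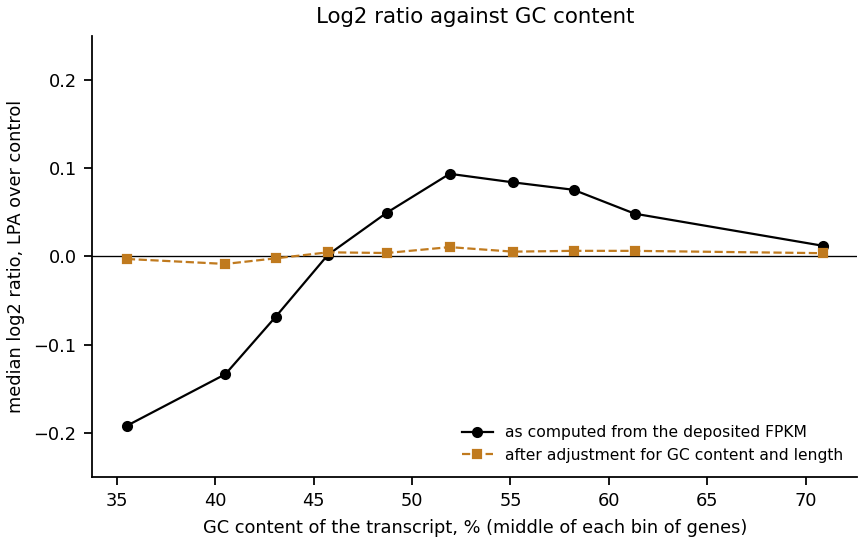
Median log2 ratio (y axis, LPA over control library) of genes in 10 bins of transcript GC content (x axis, in %), as computed from the deposited FPKM (black circles) and after adjustment for GC content and length (orange squares). The unadjusted medians go from -0.19 in the lowest bin to 0.09 in the bin from 50.3 to 53.5% and 0.01 in the highest.

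Isoform estimates differed more than gene sums. Of 16999 isoforms 678 were at least 2-fold apart with separate bounds, 372 higher and 306 lower in the LPA library, and 1368 were at least 2-fold apart without the condition on the bounds. Among 4574 genes with several isoforms, 197 had another leading isoform in each library, and 142 of these had separate bounds for at least 1 of the 2 isoforms. The biggest shift was in TUBB4A, a beta-tubulin gene, whose leading isoform in the control library held 99.6% of its FPKM there and 1.60% in the LPA library, while the gene as a whole had 23.8 and 18.3 FPKM. In IFI27 the isoform leading in the LPA library held 93.5% there and 0.098% in the control. SLC26A11, ZNF322 and DOC2A followed with shifts of 91.2, 81.1 and 76.4 percentage points. The isoforms of one gene share most of their sequence, so their split is an estimate of the software that these data cannot check against replicates.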

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

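The adjustment for GC content and length and the version with HIDATA isoforms at 0 were chosen after seeing the data; the other alternatives were fixed before. The count of genes at least 2-fold higher in the LPA library (41) became 64 with a pseudocount of 0.1, 19 with a pseudocount of 5, 21 at mean FPKM of 5 or more, 122 with the leading isoform alone and 24 without isoforms under 300 nt. The count of lower genes (24) became 57 with a pseudocount of 0.1, 15 at mean FPKM of 5 or more, 124 with the leading isoform and 7 without isoforms under 300 nt. Both counts stayed within 1.5 times of these values under the other alternatives, including the 3 other scalings (33 to 57 higher, 24 to 29 lower) and HIDATA isoforms at 0 (41 and 27). The correlation across genes was 0.972 with a pseudocount of 0.1, 0.991 without a filter and 0.975 at mean FPKM of 5 or more. The number of lists above their random range was 3 to 5 under the alternatives run for lists, which were all but the sums per gene identifier. Without a filter the list of immune markers, which has too few measured genes otherwise and is not among the 333 medians below, was above its random range (median 0.12, percentile 97.9). The number below, 1 as reported, was 2 at mean FPKM of 5 or more, where the TGF-beta list (-0.22) joined, and 3 after adjustment for GC content and length, where the fatty acid (-0.17) and interferon (-0.21) lists joined. The SRF and MRTF list left its random range with the leading isoform (0.14), and the epithelial list entered the upper side at mean FPKM of 5 or more (0.20); of the 333 alternative list medians 328 kept their call, and none moved from one side of its random range to the other. The count of isoforms with separate bounds became 1368 without the condition on the bounds and 116 at mean FPKM of 5 or more, and that of genes with another leading isoform 54 at a shift of 50 points and 81 at mean FPKM of 10 or more. Lower counts under stricter limits follow from fewer genes or isoforms being eligible, and the cause of the other differences was not tested. Among log2 ratios of genes named by rule, 935 of 986 alternative values lay within the robust SD of genes of similar expression, and none of the genes at least 2-fold apart changed sign. Depth limits low genes most, since 1 FPKM on a 2 kb isoform rests on about 31.4 to 33.5 fragments. No paired analysis was possible because the groups share a single replicate number with 1 library each.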

Other observations

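The comparisons of the synthetase, keratin and one-carbon lists and the wider lists of RNAs without a poly-A tail and of histones were chosen only after some or all of the values concerned had been seen, and so was the adjustment for GC content and length.

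Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, were higher in the LPA library for the cytosolic enzymes in 18 of 20 cases, with a median log2 ratio of 0.32 (percentile 100 among random lists). GARS was followed by CARS (30.6 and 56.1 FPKM), YARS (38.0 and 65.2 FPKM), MARS (46.8 and 79.0 FPKM) and WARS (18.2 and 30.6 FPKM), while DARS (36.2 and 26.2 FPKM) and RARS (76.8 and 67.2 FPKM) were lower. The 17 mitochondrial synthetase genes had a median of 0.12 (percentile 95.3), inside the random range. Enzymes of folate and serine one-carbon metabolism had a median of 0.17 (percentile 96.6), inside the random range, with 5 of 15 genes below 0.

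In the keratin list, which does not hold every keratin gene, 7 of 9 measured genes had a log2 ratio above 0 with a median of 0.36 (percentile 99.99). KRT81 had 0.338 FPKM in the control and 5.79 FPKM in the LPA library, KRT7 1.13 and 4.17 FPKM and KRT15 11.6 and 17.1 FPKM. KRT81 has close paralogs that can share reads. The list of epithelial junctions and keratins fixed beforehand had a median inside its random range (percentile 91.6). Other genes at least 2-fold higher, named after their values were seen, included KRT13 (0.388 and 1.93 FPKM) and the cornified envelope gene SPRR2D (0.960 and 6.51 FPKM). The aldehyde dehydrogenase genes ALDH1A1 (0.599 and 3.29 FPKM) and ALDH3A1 (0.537 and 2.14 FPKM) and IGFBP4, an IGF-binding protein gene (0.171 and 2.58 FPKM), were also higher.

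The first pattern weighed is the ATF4 and amino acid list, with the 4 other lists outside their random ranges. A GC or length trend would bring their medians into the random range, but after adjustment they were 0.61 (range -0.10 to 0.15) for ATF4, 0.19 (-0.11 to 0.13) for SRF and MRTF targets, 0.27 (-0.09 to 0.13) for G1/S, 0.31 (-0.10 to 0.15) for ribosome biogenesis and -0.19 (-0.14 to 0.13) for quiescence, so such a trend is not the whole cause. Another difference between the cultures, such as serum starvation, medium use, density or handling, cannot be told apart from LPA with 1 library per group. The cause of these differences therefore stays open.

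The second pattern is the higher level of RN7SK and RPPH1. More RNA without a poly-A tail in the LPA library could raise them. The other 15 measured RNAs of this kind had a median log2 ratio of 0.10 (random range -0.15 to 0.15, percentile 89.7), with 10 above 0 and 5 below. Of the 15, 3 were at least 2-fold higher and 1 at least 2-fold lower. The highest, RNU6ATAC (0 and 61.8 FPKM, 125 nt), and the lowest, SNORA63 (56.6 and 0 FPKM, 135 nt), are short and listed at 0 in one library. Their values are therefore uncertain. SNORD3A (150 and 443 FPKM) was higher and RN7SL1 and RN7SL2 were lower. Ribosomal RNA loci such as RNA28S5 had too many fragments to process (status HIDATA) in the LPA library only. That status goes in the direction of this explanation. Without an estimate in the LPA library the size of the difference is not known. These values leave the explanation open. The wider histone list had a median of -0.01 (percentile 53.8). A preference for short transcripts is argued against by the 127 protein-coding genes of 300 to 600 nt, whose median was -0.051 (bootstrap 95% interval -0.12 to 0.04). No biological explanation was tested, and LPA cannot be told apart here from another difference between the cultures.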
